A study of Mus musculus with 6 samples.

How the data were processed

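RNA was measured in colon tumours of mice treated with azoxymethane, a carcinogen, and dextran sulfate sodium, an irritant of the colon lining. This combination is a standard model of colitis-associated colorectal cancer. The 6 libraries came from 3 samples of Trim21 knockout mice and 3 samples of wild-type mice. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed with the GenSeq rRNA Removal Kit, and libraries were prepared with GenSeq's kit for low RNA input. The labels call the samples biological replicates. They do not say whether each sample was a tumour of its own mouse, so the p-values measure the spread between these samples.

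The authors deposited a table of whole-number read counts per gene symbol for each sample, with 26214 features in the same order in every file. Per the submitters' processing notes, the work used the mm10 build of the mouse genome, TopHat2, edgeR and limma, with no version and no statement of which step each tool served. The read counter, its handling of strand and of reads that map to several places, and the gene annotation are not given in the sources used here. No row without a gene name was found. In the deposited counts, 70 features with at least 60 reads in total share all 6 values with another feature, in 32 sets, such as Ccl21c with Gm10591 and Sprr2a1 with Sprr2a2. The members of such sets cannot be told apart. Overlapping genes on opposite strands are likewise uncertain.

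Total counts were 19987295, 17937821 and 19815389 in knockout replicates 1 to 3 and 29742757, 29629793 and 27085599 in wild-type replicates 1 to 3, so depth differs between the groups. Between 18331 and 19125 features had at least 1 read. The 5 most abundant genes took 2.18% to 2.91% of the counts of a library. The correlation of log2 CPM across genes lay between 0.946 and 0.982 for pairs of libraries. Pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom between 20.9 and 103, so every library was kept as a replicate.

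Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, on all 6 libraries, with group as the only term. Scaling used TMM factors, which ranged from 0.977 to 1.02, and low counts were removed by filterByExpr with the group, which left 16281 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05 on the adjusted p. CPM values are counts relative to the TMM-scaled library size, computed here from the deposited counts. The standard error of a log2 fold change is its size divided by the square root of the F statistic.

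Gene lists for signalling programmes, cell types and tissues that a sample could carry along were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 45 lists, 42 had at least 5 tested members. The lists for adipose tissue, pancreas and replication-dependent histones had 4, 3 and 0 tested members and were not tested. The set test was camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 42 lists. Camera with an estimated correlation and the directional fry test were run as alternatives. The number of members past the threshold is also given with p adjusted over the list alone.

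Named genes are Trim21, then genes past the test with a mean log2 CPM of at least 1 and groups that do not overlap. Sex-linked genes, antigen receptor segments and predicted or small RNA genes were left out. Since fewer than 5 genes passed in either direction, the rule gave the 8 genes with the smallest unadjusted p in each direction that met the other conditions, which are named as not passing. Up to 4 members per list with the smallest unadjusted p were also named. Positions come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, in which 24919 of the 26214 symbols were found.

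Alternatives covered DESeq2 1.42.0, limma-voom with and without sample weights, 3 other scalings, 2 other filters, the replicate number as a block, and leaving out each library. The tests were checked on counts simulated from the real means, dispersions and library sizes, with 50 genes changed at each fold size. The changed genes had a mean CPM of at least 2, so recovery at lower levels was not checked. At a log2 fold change of 1, 1.5, 2 and 3, edgeR recovered 44%, 76%, 96% and 96% of the changed genes among 16076 tested, and 11 of its 167 calls were false. DESeq2 recovered 70%, 92%, 98% and 98% among 16280 genes, and 63 of its 242 calls were false. With no gene changed, edgeR called 2 genes, DESeq2 25 and limma-voom 0. In a simulated comparison with 1 list of 41 shifted, camera called that list and no other. Genes were simulated independently of each other, so this check does not cover lists of correlated genes. In the real lists the estimated correlation reached 0.94.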

Results

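Gene expression was profiled by RNA sequencing of ribosome-depleted total RNA from colon tumours of mice that had received azoxymethane and dextran sulfate sodium. Tumours of 3 Trim21 knockout samples were compared with tumours of 3 wild-type samples. Trim21 encodes a ubiquitin ligase that also serves as a cytosolic antibody receptor. The comparison asks how loss of Trim21 alters the transcriptome of colitis-associated colon tumours. Knockout libraries held 19987295, 17937821 and 19815389 counts, and wild-type libraries held 29742757, 29629793 and 27085599 counts.

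Trim21 itself was lower but not absent in the knockout samples. It lies on chromosome 7 from 102557921 to 102565486 of mm10, on the minus strand, and is protein-coding. The knockout libraries held 244, 345 and 248 Trim21 reads and the wild-type libraries 887, 601 and 527. This corresponds to 14.6 ± 3.76 CPM in the knockout and 23.2 ± 5.68 CPM in the wild type (mean ± SD, n = 3 each), and each knockout value lay below each wild-type value. The log2 fold change was −0.67 with a standard error of 0.24, and Trim21 did not pass edgeR's quasi-likelihood test (adjusted p = 0.418). Counts per gene do not show which exons the remaining reads cover, so this check of the labels cannot settle whether a deleted segment is missing.

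Aqp8 and Clca1 had higher values and Ccdc3 lower values in every knockout tumour than in any wild-type tumour. Aqp8, a water channel of surface colonocytes, measured 30.1 ± 6.81 CPM in the knockout and 2.67 ± 1.16 CPM in the wild type. Clca1, a secreted goblet cell protein, measured 1534 ± 357 CPM against 515.6 ± 115.8 CPM. In the other direction, Ccdc3 measured 88.9 ± 4.39 CPM in the knockout and 176.1 ± 4.61 CPM in the wild type (SD, n = 3 throughout). No single gene passed the test over all 16281 genes, so these contrasts are reported as values.

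With edgeR's quasi-likelihood test, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0646, for Ccdc3. At an unadjusted p under 0.05, 1750 genes were found, 1080 higher and 670 lower in the knockout, where about 814 would be expected with no difference. The groups did not overlap for 2915 of the 16281 genes, where chance gives 10%. DESeq2 called 242 genes higher and 93 lower, and limma-voom called 0. In simulated counts of this design DESeq2 also made more false calls than edgeR did, 63 of 242 against 11 of 167. On the real counts edgeR called 0 genes, although Aqp8 had a log2 fold change of 3.50. The simulated rates may therefore not hold for these libraries.

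The 8 genes ranked first in the higher direction were Aqp8, Hpgd, Cyp3a13, Pmp22, Sdc2, Clca1, Btnl1 and Chp2, none of which passed. The log2 fold change of Aqp8 was 3.50 with a standard error of 0.36, an 11.3-fold higher level (edgeR adjusted p = 0.181). Hpgd, which degrades prostaglandins, had a log2 fold change of 1.28 (standard error 0.15, adjusted p = 0.222). Cyp3a13, a cytochrome P450 of drug and steroid oxidation, had 1.75 (standard error 0.21, adjusted p = 0.241). The myelin and epithelial membrane protein gene Pmp22 and the heparan sulfate proteoglycan gene Sdc2 both had 0.97, with standard errors of 0.12 and an adjusted p of 0.247. Clca1, Btnl1 and Chp2 had log2 fold changes of 1.57, 3.15 and 1.31, each with an adjusted p of 0.322. Btnl1, a butyrophilin-like gene of intestinal epithelium, was at a low level, with 4.57 ± 1.40 CPM in the knockout and 0.512 ± 0.225 CPM in the wild type (SD, n = 3).

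The 8 genes ranked first in the lower direction were Ccdc3, Ly6d, Lrg1, Alox15, Olr1, Pfkfb3, Clca4b and Mfsd2a, again without passing. Ccdc3 had a log2 fold change of −0.99 with a standard error of 0.08 (edgeR adjusted p = 0.0646). The other 7 genes each had an adjusted p of 0.322. Lrg1, an acute-phase glycoprotein gene, had −1.62 with a standard error of 0.24. Olr1, a scavenger receptor for oxidised lipoprotein, had −1.38 with a standard error of 0.23. Clca4b and Ly6d had −1.27 and −1.13, and the lipoxygenase gene Alox15 had −1.02. Mfsd2a, a lysolipid transporter, had −0.74, and Pfkfb3, a regulator of glycolysis, had −0.59. DESeq2 called all 16 of these genes, and Ccdc3 was also called by limma-voom with sample weights (log2 fold change −0.96, adjusted p = 0.0379).

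**Figure D1:**
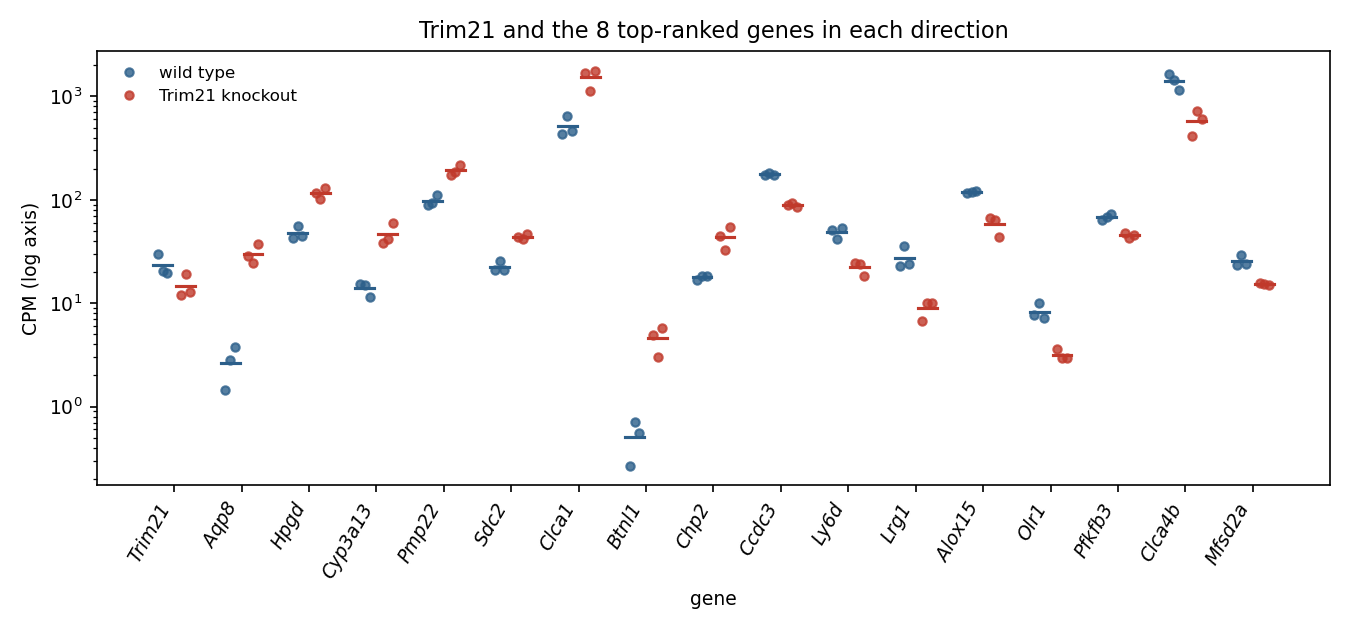
CPM on a log axis of Trim21 and of the 8 top-ranked genes in each direction, with a point per library and a line at the group mean (n = 3). The groups do not overlap for any gene shown, which the rule for named genes required of all but Trim21. Aqp8 lies at 24.2 to 37.5 CPM in the knockout libraries and at 1.44 to 3.74 CPM in the wild-type libraries.

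Of the 42 gene lists, 19 passed the set test with a preset correlation of 0.01, 13 of them higher and 6 lower in the knockout. With an estimated correlation, 0 of the 42 passed, and with the directional fry test 0 passed, with smallest adjusted p of 0.701 and 0.408. No list had a member past the test over all genes. Counts of members given below are therefore adjusted over the list alone.

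Markers of differentiated epithelium ranked higher in knockout tumours. In the mature colonocyte list, 19 of 21 tested genes had a positive log2 fold change, the median was 1.32, and 12 members were higher adjusted over the list alone. Besides Aqp8, these included the sodium channel subunit gene Scnn1g (log2 fold change 2.29), the phosphate transporter gene Slc20a1 (0.86) and Hsd11b2 (2.19), which inactivates glucocorticoids. The camera adjusted p was 4.09e-08, and it was 0.701 with an estimated correlation. The goblet cell list had a median of 0.82 over 16 genes, with 5 higher adjusted over the list alone, among them Clca1, Zg16 (2.19), Fer1l6 (1.73) and Fcgbp (1.56). Its adjusted p was 7.86e-07, and 0.701 with an estimated correlation. Leaving out single libraries put the median of the goblet list between 0.57 and 1.49, the highest without wild-type replicate 2. Its mean log2 CPM was 7.83, 7.15 and 7.55 in knockout replicates 1 to 3 and 5.51, 7.30 and 6.51 in wild-type replicates 1 to 3, so the groups overlapped. The enteroendocrine list had a median of 1.26 over 12 genes, all with positive values. The hormone genes Gcg (2.36) and Pyy (2.15), the serotonin-synthesis gene Tph1 (0.99) and Chga (1.45) were the 4 members higher adjusted over the list alone. Its adjusted p was 3.28e-06, and 0.701 with an estimated correlation. Wild-type replicate 1 stood apart in the enteroendocrine list, at a mean log2 CPM of 0.264 against 1.29 to 2.81 in the other 5 libraries. With the smooth muscle score as a covariate, chosen after seeing the data, the mature colonocyte median fell from 1.32 to 0.29 (adjusted p = 0.00151), and neither the goblet list (median 0.10, adjusted p = 0.513) nor the enteroendocrine list (median 0.42, adjusted p = 0.109) passed.

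Muscle and stromal markers moved the same way as these epithelial lists. The smooth muscle list had a median of 0.91 over 15 genes, and Mylk (0.50), Myl9 (1.11) and Acta2 (1.00) were higher adjusted over the list alone (camera adjusted p = 7.86e-07, and 0.701 with an estimated correlation). Its mean log2 CPM was 5.82, 5.29 and 5.45 in knockout replicates 1 to 3 and 3.56, 5.17 and 4.86 in wild-type replicates 1 to 3. Wild-type replicate 1 was also lowest for the mature colonocyte list, at 3.98 against 5.08 to 6.24 in the other 5 libraries. The fibroblast and matrix list had a median of 0.35 over 22 genes, with the collagen genes Col6a1 (0.61) and Col6a2 (0.70) higher adjusted over the list alone. Its adjusted p was 0.00187, and 0.821 with an estimated correlation. Without wild-type replicate 3 it was 0.0935, with a median of 0.23, and the median was 0.54 without knockout replicate 1 and 0.22 without knockout replicate 3. The endothelial list had a median of 0.27 over 15 genes, with Vwf (0.42) and Plvap (0.54) higher adjusted over the list alone (adjusted p = 0.01, and 0.821 with an estimated correlation). The mean log2 CPM of the fibroblast list and of the endothelial list overlapped between the groups. The enteric neuron and glia list had a median of 0.70 over 14 genes (adjusted p = 0.018, and 0.701 with an estimated correlation). Its member Ret, a receptor tyrosine kinase gene, went the other way at −0.86 and was lower adjusted over the list alone, while Stmn2 had 1.27. The endothelial call ended without knockout replicate 2 or 3 or wild-type replicate 1 or 2 (medians 0.13, 0.16, 0.14 and 0.24, adjusted p = 0.0644, 0.125, 0.109 and 0.0639), and its median was 0.43 without knockout replicate 1. The neuron and glia call ended without knockout replicate 1 (median 0.51, adjusted p = 0.105) or wild-type replicate 1 (median 0.39, adjusted p = 0.0728), and its median was 1.22 without wild-type replicate 2. That call also ended with DESeq2 (median 0.80, adjusted p = 0.0619), limma-voom with sample weights (0.87, 0.0954) and a filter of CPM at least 1 in 3 libraries (0.70, 0.0529). The median did not shrink in these settings.

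**Figure D2:**
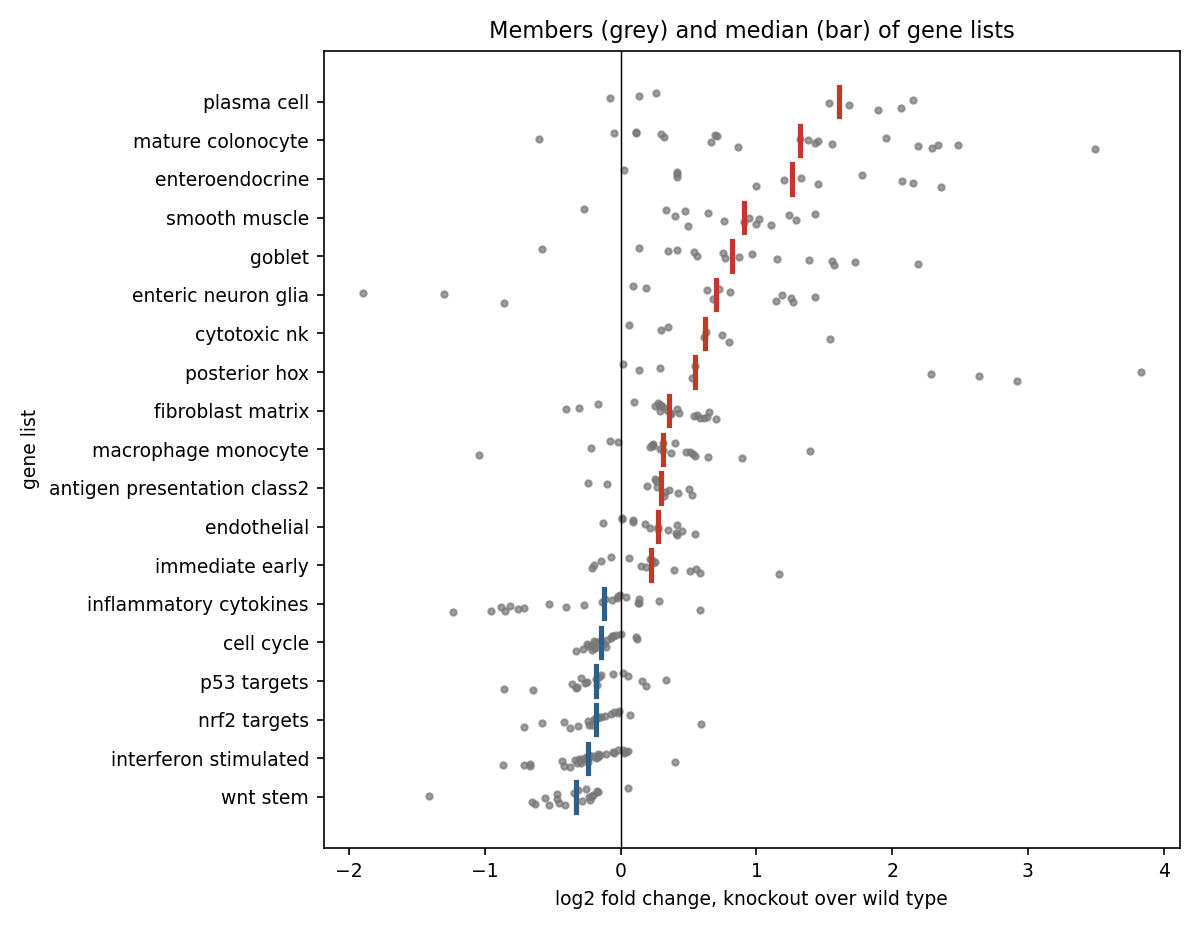
Log2 fold change of each tested member (grey points) and the median (bar) for 18 lists past the set test and for the interferon-stimulated list, with red for medians above 0 and blue for medians below 0. The skeletal muscle list, with a median of −6.87, is left out of the plot, and the shown medians run from −0.33 for the Wnt and stem cell list to 1.61 for the plasma cell list.

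Among immune cell markers, plasma cell genes had the largest median. It was 1.61 over 8 tested genes, and Mzb1 (1.90), Jchain (2.07), Irf4 (1.69) and Pou2af1 (1.54) were higher adjusted over the list alone (camera adjusted p = 0.00691, and 0.701 with an estimated correlation). Without knockout replicate 3 the plasma cell median was 1.06 (adjusted p = 0.039). Jchain measured 1779 ± 1086 CPM in the knockout and 424.8 ± 208.2 CPM in the wild type (SD, n = 3). The macrophage and monocyte list had a median of 0.31 over 20 genes, with Ccr2 at 0.89 and Mrc1 at 0.64 but Arg1 at −1.05 (adjusted p = 0.000397, and 0.701 with an estimated correlation). The cytotoxic and natural killer cell list had a median of 0.62 over 8 genes at levels near 1 CPM, such as Klrd1 at 1.11 ± 0.161 and 0.636 ± 0.0949 CPM (SD, n = 3). Its adjusted p was 0.014, and 0.701 with an estimated correlation, and without knockout replicate 3 the median was 0.28 (adjusted p = 0.362). The list of antigen presentation by class II molecules had a median of 0.29 over 12 genes, with Ctss at 0.52 (adjusted p = 0.0407, and 0.821 with an estimated correlation). That call ended without knockout replicate 2 or 3 or wild-type replicate 1 or 2 (medians 0.18, 0.32, 0.09 and 0.31, adjusted p = 0.282, 0.125, 0.499 and 0.109), and its median was 0.48 without knockout replicate 1 and 0.46 without wild-type replicate 3.

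T cell, B cell, neutrophil, dendritic cell and mast cell lists did not pass, with medians of 0.39, 0.28, −0.23, 0.11 and −0.18 and camera adjusted p of 0.18, 0.13, 0.469, 0.47 and 0.929. Leaving out wild-type replicate 3 took the T cell, B cell and neutrophil lists past the threshold (adjusted p = 0.00931, 0.000476 and 0.00931). Leaving out knockout replicate 1 did so for T cells, B cells and dendritic cells (0.00791, 0.0337 and 0.0325). With sample weights in limma-voom the T cell list passed (0.0432). Neutrophils also passed without knockout replicate 3 (0.0125), and mast cells without wild-type replicate 2 (0.0176). With every other omission of a single library these lists did not pass. Their mean log2 CPM overlapped between the groups, so these gained calls rest on single libraries. The plasma cell, macrophage, cytotoxic and class II lists, which passed, overlapped between the groups as well. For plasma cells, knockout replicate 1 was at 4.06 and wild-type replicate 3 at 4.25. The immune checkpoint list had a median of 0.07, opposite in sign to its test direction, and an adjusted p of 0.932. In the type 17 list the median was 0.06 and the adjusted p 0.814.

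Wnt and stem cell genes ranked lower in knockout tumours. The list had a median of −0.33, with 19 of 20 genes below 0, and its first members were the receptor gene Ephb3 (−0.41), the Wnt regulators Znrf3 (−0.53) and Rnf43 (−0.45) and the transcription factor gene Lef1 (−0.63). No member passed adjusted over the list alone. The camera adjusted p was 3.76e-05, and 0.701 with an estimated correlation, and the median was −0.53 without knockout replicate 1. Targets of the oxidative stress factor Nrf2 had a median of −0.18 with 18 of 20 genes below 0, including Txnrd1 (−0.37), Slc7a11 (−0.71), Prdx1 (−0.32) and Gclm (−0.24). Their adjusted p was 0.00142, and 0.701 with an estimated correlation. The p53 target list had a median of −0.18 over 18 genes, with Phlda3 (−0.65), Eda2r (−0.86) and Aen (−0.33) lower adjusted over the list alone (adjusted p = 0.0263, and 0.821 with an estimated correlation). It did not pass without knockout replicate 1 or wild-type replicate 2 or 3 (medians −0.13, −0.14 and −0.19, adjusted p = 0.184, 0.144 and 0.17), and its median was −0.29 without knockout replicate 3 and −0.28 without wild-type replicate 1. The cell cycle list had a median of −0.15, with 20 of 22 genes below 0, and Mki67 had −0.20 (adjusted p = 0.0384, and 0.875 with an estimated correlation). It did not pass without knockout replicate 2 or 3 or wild-type replicate 1 or 3 (medians −0.13, −0.03, −0.11 and −0.06, adjusted p = 0.165, 0.661, 0.129 and 0.441), and its median was −0.31 without knockout replicate 1 and −0.23 without wild-type replicate 2.

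Inflammatory cytokine and acute-phase genes had a median of −0.13 over 22 genes, with Lcn2 at −1.24, Osm at −0.96 and Nos2 at −0.85 but Il1rn at 0.58. The camera adjusted p was 0.0384, and 0.821 with an estimated correlation. It was 0.58, 0.054 and 0.584 without knockout replicate 1, knockout replicate 2 and wild-type replicate 2, where the median was 0.00233, −0.13 and 0.10, so its sign turned in the first and last. The median was −0.57 without knockout replicate 3, and −0.24 without wild-type replicate 1 or wild-type replicate 3. The antimicrobial list did not pass (median −0.55 over 13 genes, adjusted p = 0.312), and 4 members were lower adjusted over the list alone. They were the protease gene Mmp7 (−1.001), the phospholipase gene Pla2g2a (−0.73) and the oxidase pair Duox2 (−0.55) and Duoxa2 (−0.79). Immediate early genes had a median of 0.22 over 16 genes, with Klf4 (1.17) higher adjusted over the list alone and Fos at 0.59 (adjusted p = 0.0384, and 0.701 with an estimated correlation). That list did not pass without knockout replicate 3 (median 0.10, adjusted p = 0.241) or wild-type replicate 3 (median 0.22, adjusted p = 0.141). The posterior Hox list had a median of 0.55 and a mean of 1.46 over 9 genes (adjusted p = 0.0247, and 0.701 with an estimated correlation). Hoxd13 measured 3.62, 117.9 and 38.7 CPM in the knockout replicates and 8.12 to 9.38 CPM in the wild type. The Hox call ended without knockout replicate 2 or 3 or wild-type replicate 1 or 3 (medians 0.63, 0.99, 0.35 and 0.83, adjusted p = 0.0644, 0.0545, 0.187 and 0.0637), and its median was 1.07 without knockout replicate 1 and 1.06 without wild-type replicate 2.

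Interferon-stimulated genes, which Trim21 is known to act on through interferon regulatory factors, did not pass the set test as a list. The median was −0.24 over 31 genes and the camera adjusted p 0.0864. Mean log2 CPM was 3.87, 5.98 and 4.69 in knockout replicates 1 to 3 and 6.14, 4.66 and 4.82 in wild-type replicates 1 to 3, so a library of each group stood high. Ifit1, for example, measured 155.1 CPM in knockout replicate 2 and 199.6 CPM in wild-type replicate 1, and 16.6 to 77.0 CPM in the other libraries. Without knockout replicate 2 the list was lower (median −0.99, adjusted p = 7.5e-08), and it was also lower without wild-type replicate 2 (−0.47, 0.0087) or wild-type replicate 3 (−0.41, 0.0162). The median was positive without wild-type replicate 1 (0.39, 0.557) or knockout replicate 1 (0.15, 0.58), and −0.04 without knockout replicate 3 (0.208), so its sign depends on single libraries. With limma-voom on all libraries it was lower (−0.37, 0.0356), and with sample weights higher (0.385, 0.0112). The estimated correlation between these genes was 0.929, with which the adjusted p on all libraries was 0.881, while the calls above rest on the preset correlation of 0.01. The nucleic acid sensing list had a median of −0.06 (adjusted p = 0.312), with Sting1 at −0.61 and Cgas at −0.30. Class I antigen presentation had a median of 0.17 (adjusted p = 0.428), and it passed without knockout replicate 1 (0.00198) and with sample weights in limma-voom (0.00152).

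**Figure D3:**
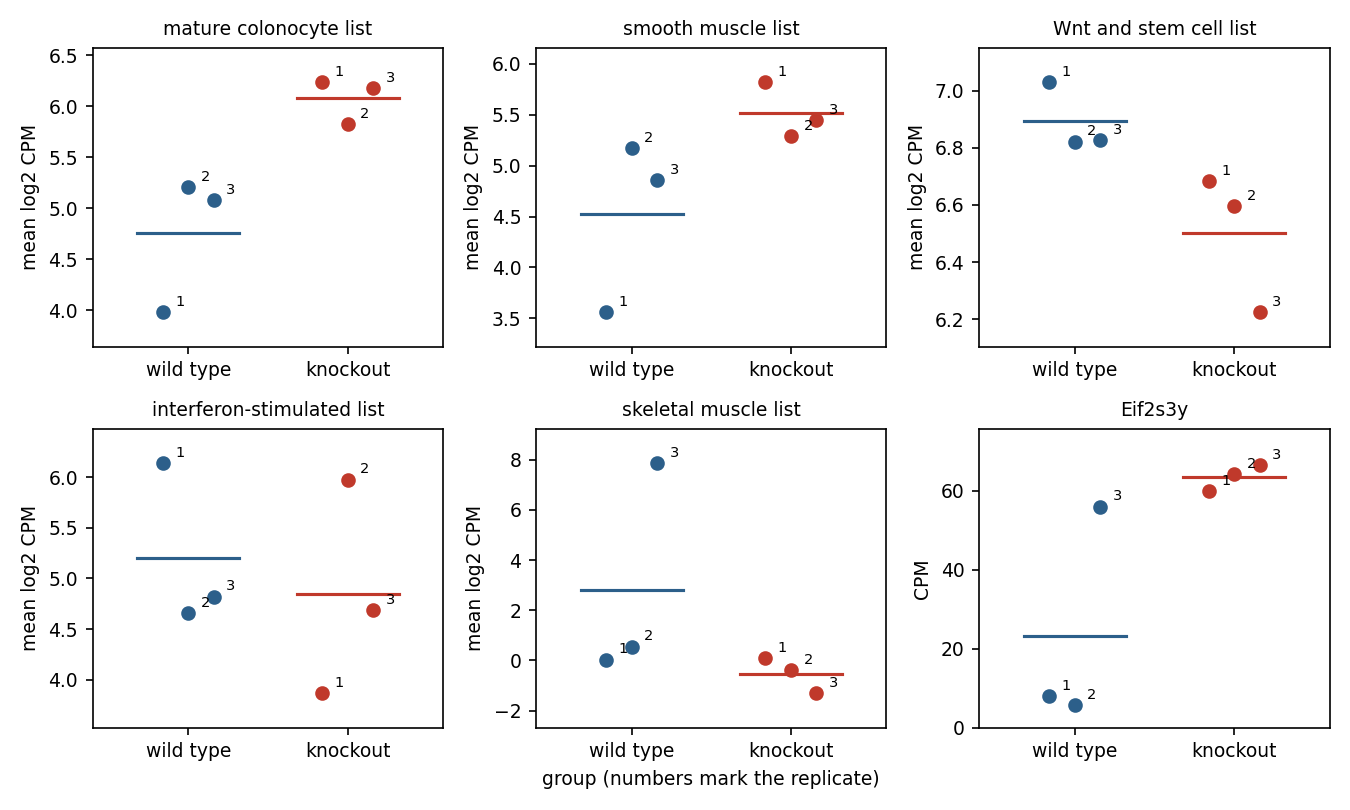
Mean log2 CPM of 5 gene lists and CPM of Eif2s3y in each library, with replicate numbers beside the points and a line at the group mean (n = 3). The mature colonocyte values of the knockout libraries, 5.83 to 6.24, lie above the wild-type values, 3.98 to 5.21, while the interferon-stimulated list is high in knockout replicate 2 and wild-type replicate 1.

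The next 5 lists, of metabolism and stress, did not pass the set test. Median log2 fold changes were 0.14 for fatty acid and PPAR genes, 0.11 for oxidative phosphorylation, 0.05 for cholesterol synthesis, −0.10 for hypoxia and glycolysis, and −0.09 for the unfolded protein response. Their camera adjusted p were 0.0746, 0.0864, 0.312, 0.363 and 0.265. Fatty acid and PPAR genes passed with DESeq2 (0.041) and limma-voom (0.0356), and oxidative phosphorylation with limma-voom (0.0427). Without wild-type replicate 3 these 2 lists passed (both 0.00474), oxidative phosphorylation also passed without knockout replicate 2 (0.0252), and hypoxia and glycolysis passed without wild-type replicate 2 (0.0475). The unfolded protein response passed with sample weights in limma-voom (0.0217) and without knockout replicate 3 (0.03) or wild-type replicate 1 (0.0116). Fetal-type regenerative genes and regulators of epithelial-mesenchymal transition both had a median of 0.14 (adjusted p = 0.891 and 0.837). Pan-epithelial genes had a median of 0.11 (0.242) and tuft cell genes 0.21 (0.312), the latter passing without knockout replicate 3 (0.03), with DESeq2 (median 0.50, adjusted p = 0.0363) and with no low-count filter (median 0.50, adjusted p = 0.0336). Erythroid genes had a median of −0.74 (0.18), and passed without wild-type replicate 1 (0.00172) and with sample weights in limma-voom (0.002). Squamous and anal epithelial genes had a median of −0.06 (0.312), with the keratin gene Krt4 at −2.56 and lower adjusted over the list alone.

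Skeletal muscle genes were high in wild-type replicate 3 alone. The list had a median of −6.87 over 9 genes (camera adjusted p = 0.00612, and 0.821 with an estimated correlation), and all 9 were lower in the knockout adjusted over the list alone. The fast myosin gene Myh4 measured 1418 CPM in that library and 0.0517 to 4.81 CPM in the other 5. The 13 genes of the list took 0.358% of the counts of that library and at most 0.00178% elsewhere, and without that library the median was −0.91 (adjusted p = 0.0036). With limma-voom on all libraries the median was −3.13 and the list did not pass (adjusted p = 0.114).

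All 6 libraries had a male pattern of sex-linked expression. Xist had 4 to 107 reads per library, while Ddx3y had 1851 to 3319, Kdm5d 969 to 1563 and Uty 728 to 1680. Eif2s3y had 1170 to 1509 reads in 4 libraries but 237 and 167 in wild-type replicates 1 and 2. The sex-linked list did not pass the set test (median 0.09, mean −0.135, adjusted p = 0.814). Within 10 Mb of Trim21, 0 of 170 tested genes passed edgeR's test, and 0 of 15617 passed elsewhere, so the planned comparison of these shares had nothing to compare.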

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

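The robust edgeR fit, thinning and the smooth muscle covariate were chosen after seeing the data. The counts of 0 genes higher and 0 lower held in all scalings, filters, limma-voom, the replicate block and the 3 added settings. DESeq2 gave 242 higher, 93 lower and 6 genes near Trim21. How many genes near Trim21 it tested is not given here, so the 6 cannot be read as an excess. Among all 17168 genes with a DESeq2 adjusted p, 335 were called. Of these 335 genes, 329 had an unadjusted edgeR p under 0.05, and the cause of the difference between the tools was not tested on these libraries. Leaving out 1 library gave 0 to 1 genes higher, the 1 being Eif2s3y without wild-type replicate 3 (log2 fold change 3.22, adjusted p = 0.0228). Sample weights in limma-voom and an adjusted p under 0.1 in edgeR each gave 1 gene lower, Ccdc3 in both. The log2 fold change of Trim21 ranged from −0.90 to −0.22 and its adjusted p from 0.216 to 0.944. The 16 ranked genes kept their sign in all settings, which their selection for groups that do not overlap made nearly certain. Of the lists, 19 passed, with 15 to 23 in the other settings, but 0 with an estimated correlation and 0 with fry, which also asks another question. Interferon-stimulated genes turned to a median of 0.385 with sample weights (adjusted p = 0.0112) and 0.965 with the smooth muscle covariate (7.18e-07). The sample weights were 3.27 for knockout replicate 2 and 0.445 for wild-type replicate 1, the libraries highest for these genes. Wild-type replicate 1 also had the lowest smooth muscle score, at 3.56 against 4.86 to 5.82 in the other libraries. Oxidative phosphorylation turned to −0.0975 and enteric neurons and glia to −0.352 with the smooth muscle covariate. It also took inflammatory cytokines from −0.126 to −0.342 and p53 targets from −0.181 to −0.315. With the smooth muscle covariate the smooth muscle, endothelial, cell cycle, class II, immediate early and Hox lists lost their calls. Their adjusted p were 0.184, 0.0806, 0.128, 0.663, 0.0547 and 0.449, with medians of 0.232, 0.159, −0.128, 0.0507, 0.198 and 0.182. The covariate is the mean log2 CPM of the smooth muscle list itself, so the loss for that list was built in. The cell cycle and immediate early medians moved little, from −0.145 and 0.223. The class I (0.00532), unfolded protein response (0.00532) and erythroid (3.59e-09) lists passed with this covariate. Thinning ended the class II call (adjusted p = 0.0539), though its median was 0.302 against 0.294 in the main fit. The causes were not tested. Libraries with the same number in their titles showed no pairing, with correlations of their deviations of −0.147, −0.175 and −0.0734. The submitters' own sample numbers differ, and match in only 2 pairs of libraries, with 0.0272 and −0.0734. The replicate block gave 0 genes and 21 lists, with T cells (0.0219) and B cells (0.00665) gained. Knockout libraries are shallower, so genes at a few reads, such as the cytotoxic cell markers, are the least certain.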

Other observations

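Several genes outside the lists were chosen here after their values were seen, and none passed edgeR's test over all genes. No list or set test covers them, so they stand for single genes only. In knockout against wild-type tumours, the kinase gene Sgk1 measured 123.1 ± 24.6 CPM against 50.05 ± 10.95 CPM, the potassium pump gene Atp12a 107.8 ± 49.0 against 24.4 ± 8.53, and Scnn1a 50.6 ± 7.71 against 29.3 ± 12.97 (SD, n = 3). The log2 fold change was 0.58 for the mineralocorticoid receptor gene Nr3c2 and 1.19 for Fkbp5, a glucocorticoid target. Among genes of detoxifying enzymes, Ces2a was at 2.20, Ces2c at 1.91, Cyp2c68 at 2.38, Cyp4f14 at 1.90 and Sult1d1 at 1.79. Ccl21b had 1.54 and Ccl21c 1.56, a pair of near-identical chemokine genes, and Ccl21c shares every count with Gm10591, so their values are uncertain.

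Values of circadian clock genes lay on both sides of 0. Per2 measured 65.8 ± 14.03 CPM in knockout and 26.9 ± 8.18 CPM in wild-type tumours, and Per3 34.3 ± 7.16 and 16.9 ± 2.27 CPM (SD, n = 3). Log2 fold changes were 0.64 for Per1, 0.54 for Cry1, 0.74 for Tef, 1.45 for Hlf, 1.003 for Dbp and 0.36 for Arntl, and −0.14 for Nr1d1, 0.04 for Nr1d2, −0.15 for Clock and 0.00 for Npas2. The hour of collection is not given in the sources used here.

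The tests with the smooth muscle score, thinning, skeletal muscle, another tissue, female cells, genes near Trim21, and splits by edgeR and unadjusted p were chosen only after the results were seen, as was the use here of the planned omission of wild-type replicate 1. Mature colonocyte markers were higher in knockout tumours, with a difference in mean log2 CPM of 1.33 (standard error 0.411). Camera ranks the genes of the list against other genes and does not test that difference between samples. It gave an adjusted p of 4.09e-08, or 0.701 with an estimated correlation. Thinning every library to 17937821 counts left the median log2 fold change at 1.39. Thinning keeps the expected share of each gene in its library, so it could hardly have moved this median. It therefore does not decide whether depth plays a part. More muscle-bearing colon wall in the knockout samples stays open, also as the whole cause. With the smooth muscle score as a covariate the difference was 0.555 (standard error 0.135), and 0.285 remained after subtracting 2 standard errors. The median log2 fold change fell to 0.29 (camera adjusted p = 0.00151). The score is an imperfect measure of wall share, so this remainder cannot exclude wall share as the whole cause. Nor can wall share as most of the difference be told apart, because the score itself differs between the groups. With this covariate the goblet list (adjusted p = 0.513) and the enteroendocrine list (0.109) no longer passed. Wild-type replicate 1 also stays open as a contributor, since without it the median was 0.943. Camera at the preset correlation still called the list then (adjusted p = 1.82e-07). A bootstrap 95% interval of that median, 0.179 to 1.41, resampled the genes of the list and does not measure the spread between samples. An effect of the genotype on differentiation was not tested.

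In wild-type replicate 3 all 9 tested skeletal muscle markers were more than 10 times the highest of the other 5 libraries, with a smallest ratio of 33.3. This restates the pattern, so skeletal muscle in that sample stays open. Ttn and Mb, chosen afterwards, measured 527.6 and 180.8 CPM there and at most 4.16 and 0.474 CPM elsewhere. A sample of another tissue under this label is argued against, as its pan-epithelial score was 0.401 above the lowest of the other 5 libraries. Prol1 and 2310057J18Rik measured 6432 and 8181 CPM in the same library and 0.465 to 23.1 CPM elsewhere, from a source that was not tested.

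Eif2s3y, on chromosome Y from 1010543 to 1028847, averaged 6.80 CPM in wild-type replicates 1 and 2 and 61.7 CPM in the other 4 libraries. Female cells in those samples are argued against, because Ddx3y, Kdm5d and Uty stood at 1.10 times their level elsewhere. Reads assigned to the X-linked copy Eif2s3x are argued against as well. Eif2s3x was 14.6 CPM higher in these libraries, where 54.9 CPM of Eif2s3y were lacking. A Y chromosome of another origin in these animals was not tested and stays open.

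A knockout allele can carry flanking DNA of another strain. Within 10 Mb of Trim21, 25 of 170 genes had an unadjusted p under 0.05, or 14.7%, against 10.7% elsewhere (Fisher exact p = 0.105), which leaves this open.

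The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. By edgeR all 10 splits gave 0 genes, so 10 were as large as the real one. At an unadjusted p under 0.05 the real split gave 1750 genes and the highest other 1148, and DESeq2 gave 335 and 134, so only 1 split, the real one, was as large in each. For gene lists past camera, 3 splits gave at least 19, and the highest other gave 25.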
